A study of Homo sapiens with 8 samples.

How the data were processed

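Total RNA of the PEO1 and PEO4 ovarian cancer cell lines was profiled on Affymetrix human GeneChip arrays in high-throughput format, with 4 arrays per line and 1 sample per array. Per the labels' protocols, cells were grown in 10 mL of RPMI medium with 10% serum. The authors deposited 1 table of log2 values, with a row for each of 22277 probe sets and a column for each array. RMA and affy 1.28.0 are named in the submitters' processing notes. RMA subtracts background, makes the arrays' distributions alike (quantile normalization) and summarises each probe set on a log2 scale. The scale itself is not stated and was read from the values, which are continuous, lie between 4.16 and 15.37 and have lower quartiles of 5.13 to 5.19 and upper quartiles of 9.02 to 9.07 on all arrays. RMA compresses differences of dim transcripts, so their folds are understated, and a shift of most transcripts in one direction would be removed. The scanner images, detection calls, scan dates and genome build are not given in the sources used here, so no batch could be tested.

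Probe sets were named through the platform annotation, with symbols looked up by Entrez ID in the gene table of assembly GRCh38.p14. Of 22215 probe sets other than the 62 controls, 19724 had 1 gene symbol, 568 had several and 1923 were not named. The symbols of 0 probe sets changed in the look-up, and the Entrez ID of 17 was not found. No chromosome positions are printed, because the deposited data name no genome build. The gene table served only for names and for which genes neighbour each other. Each of 12165 genes was represented by the probe set with the highest mean over all 8 arrays; 4505 genes had more than 1. Of 1951 called genes with another probe set, 1276 had another one past the threshold in the same direction and 32 in the opposite direction. The 12 Bacillus control probe sets read 4.34 to 5.18 and were taken as a background range. A gene within it on all 4 arrays of 1 line only (668 genes) has no measured level there, and its fold is given as a bound against the top of that range; 1482 genes were within it in both lines. Where only the mean and 3 of 4 arrays of a line lay within it, the fold of a gene named in the report is also a bound.

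Differences are PEO4 minus PEO1. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no intensity filter, no replicate block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; a size threshold of 2-fold is reported beside it. SE is the moderated standard error of the log2 difference and SD the spread of the 4 arrays. The 29 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation. The mean of each list per array was compared with an exact permutation test. The design, the 29 lists, the alternatives and the genes to name were chosen before the data were examined. Named genes were the 10 with the largest difference in each direction among called genes whose arrays did not overlap between lines, leaving out XIST and Y-linked genes; the 2 most increased and 2 most decreased called members of each list; and 12 fixed genes, of which 10 were analysed here. Any further gene given with a value was named after its values were seen, whether or not this is said beside it.

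The fit was tested on simulated data: values for the 12165 genes of this comparison were drawn from the real means and spreads with known changes in a set of genes. It recovered 77.6% of 67 genes changed by 0.5 on the log2 scale, 100% of 67 changed by 1 and 100% of 66 changed by 2. Of the calls 5.48% were false, and camera ranked the 1 shifted list first. Few of the 12165 genes were changed in the simulation, while 37.9% were called in the real comparison, so these percentages need not hold there. Genes were drawn independently of each other, so the simulation does not show how camera behaves when the genes of a list are correlated. The alternatives were the mean of a gene's probe sets, all probe sets separately, leaving out probe sets with an _s_at or _x_at suffix, only genes at log2 6 or above on at least 4 arrays, a trended robust prior, array weights, centring on housekeeping genes, cyclic loess, a replicate block, leaving out each array, an estimated list correlation and a test against 1.5-fold. Figures were drawn with matplotlib 3.10.9.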

Results

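Gene expression was measured in PEO1 and PEO4, a pair of established human ovarian cancer cell lines, on 8 Affymetrix human GeneChip arrays. This array reads each transcript through a probe set, a group of short oligonucleotides. PEO1 is labelled platinum-sensitive and PEO4 platinum-resistant, and each line had 4 replicate arrays. The labels do not say whether replicates came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. The design holds 1 sensitive and 1 resistant line, so a difference between them is a difference between the lines. The values are log2 RMA values from 4.16 to 15.37, with array medians from 6.32 to 6.38. Pearson correlations across probe sets were 0.995 to 0.997 between PEO1 arrays, 0.996 to 0.997 between PEO4 arrays and 0.968 to 0.971 between lines. The first principal component separated the lines and held 84.4% of the variance across genes. The median within-line SD of a gene was 0.124 in PEO1 and 0.115 in PEO4 on the log2 scale. The GAPDH control probe sets, which compare the 3′ and 5′ ends of the transcript as a sign of RNA integrity, differed by -0.206 ± 0.017 (SD, n = 4) in PEO1 and -0.209 ± 0.017 in PEO4. The same difference for ACTB was 0.102 ± 0.062 in PEO1 and 0.214 ± 0.108 in PEO4. Arrays carry no count of molecules, so the number of arrays limits the precision.

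The comparison asked which transcripts differed between the platinum-resistant and the platinum-sensitive line. Of 12165 genes, 4605 (37.9%) differed at an adjusted p under 0.05 in limma's moderated test, 2336 higher and 2269 lower in PEO4. A difference of at least 2-fold was found for 485 genes higher and 452 lower in PEO4, 937 in all. A difference of at least 8-fold was found for 40 genes higher and 39 lower. The 4 arrays of one line lay entirely above or below the 4 of the other for 4450 genes (36.6%), against 2.86% expected by chance. Calls were 50.7% higher in PEO4 on the deposited scale, and 36.4% when arrays were centred on a fixed list of housekeeping genes, a scaling that moved the median of all genes by -0.092 on the log2 scale.

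Among the 10 largest increases, 7 were genes of the antiviral interferon response. IFIT1, an RNA-binding antiviral protein, rose from 5.85 ± 0.25 (SD, n = 4) in PEO1 to 11.74 ± 0.30 in PEO4, 59.3-fold higher. The log2 difference (± SE) was 5.83 ± 0.21 for IFITM1, 5.54 ± 0.16 for MX1, 5.53 ± 0.096 for IFI44, 5.47 ± 0.18 for RSAD2, 5.24 ± 0.076 for IFI6 and 4.64 ± 0.12 for OASL. The largest increase was that of AKR1D1, a reductase of steroid and bile acid metabolism, at 12.05 ± 0.19 in PEO4 and 4.87 ± 0.036 in PEO1. Its 4 PEO1 arrays lay within the range of the Bacillus control probe sets (4.34 to 5.18), so its increase is given as at least 117-fold higher than the top of that range. ZFPM2, a cofactor of GATA transcription factors, was at least 31.4-fold higher by the same rule. CRABP2, a retinoic acid-binding protein, rose by 5.29 ± 0.23, 39.2-fold. RSAD2 was within the control range on 1 of its 4 PEO1 arrays, and the other IFI44 probe set was higher by less (1.82). The adjusted p of these 10 genes in limma ranged up to 1.68e-08.

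The largest decrease was that of PROM1, which encodes the surface marker CD133, from 12.53 ± 0.14 (SD, n = 4) in PEO1 to 5.12 ± 0.13 in PEO4. Its PEO4 mean and 3 of its 4 PEO4 arrays lay within the control range, so its decrease is given as at least 163-fold, against the top of that range. The same held for IL1R2, a decoy receptor for interleukin 1, at least 78.8-fold lower, with -5.48 on its other probe set. DIRAS3, an imprinted Ras-related gene, had a log2 difference of -6.33 ± 0.094 (SE), and KRT5, a basal keratin, -5.84 ± 0.068. The other log2 differences were -5.69 ± 0.19 for SCG5, -5.36 ± 0.24 for INHBB, -5.14 ± 0.12 for BEX1, -5.11 ± 0.15 for PLCB4 and -4.96 ± 0.098 for PXDN. INHBB encodes an inhibin and activin subunit, and PLCB4, within the control range on 1 of its 4 PEO4 arrays, a phospholipase C. EHF, an epithelial ETS transcription factor, was within the control range on all PEO4 arrays and at least 23.9-fold lower. The adjusted p of these 10 genes in limma ranged up to 1.96e-08.

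**Figure D1:**
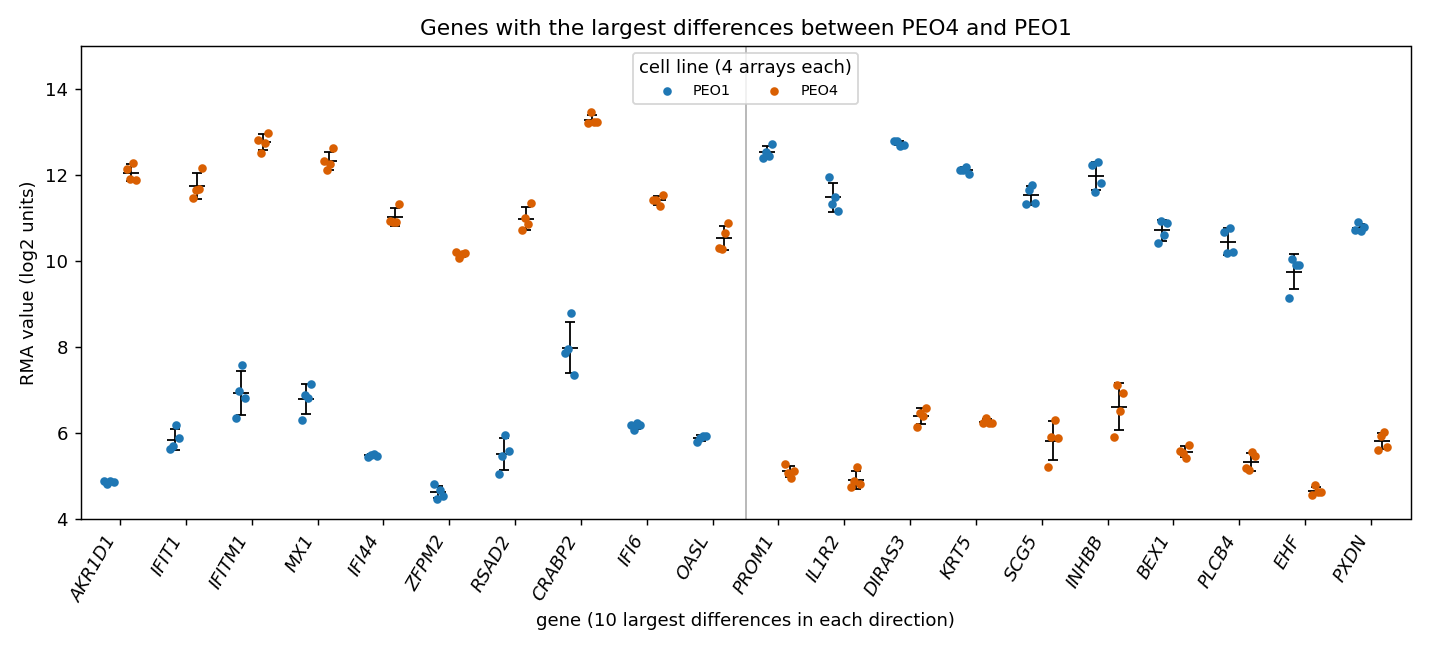
RMA value (log2 units) on each array for the 10 genes with the largest increase and the 10 with the largest decrease in PEO4. Points are single arrays (4 per line) and bars are the mean and SD; the lines do not overlap for any of these genes, and AKR1D1 lies at 4.87 on average in PEO1 and 12.05 in PEO4.

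Interferon-stimulated genes had the largest median difference of the 29 fixed lists. 31 of the 34 measured members were higher in PEO4, 29 of them at least 2-fold, and none was lower; adjusted over the list alone, 31 passed. The median difference was 2.93 on the log2 scale, 7.63-fold. The mean of the list was 7.18 ± 0.14 (SD, n = 4 arrays) in PEO1 and 10.14 ± 0.17 in PEO4. The 3 members that did not pass, named after their values were seen, were GBP1 (0.44 ± 0.31), GBP2 (0.12 ± 0.11) and MX2 (0.05 ± 0.12). Relative to all other genes the list was higher by limma's camera test with a preset correlation (adjusted p = 1.12e-26). With an estimated correlation the adjusted p was 0.264. An exact two-sided permutation test of the list mean per array gave p = 0.0286, the smallest that 4 against 4 arrays can give, and 0.046 after adjustment over the 29 lists; 18 of the 29 lists gave these values, so this test does not set the list apart. IFITM1, IFITM2 and IFITM3 are near-identical copies whose probe sets can share signal. Leukocyte markers had a median log2 difference of 0.036, and 2 of 16 rose.

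Genes of antigen processing and presentation were the other list past the threshold at the preset correlation (camera adjusted p = 2.64e-05), though not at an estimated one (0.264). 17 of the 27 measured members were higher in PEO4, 6 of them at least 2-fold, 1 was lower and 9 did not pass; adjusted over the list alone, 18 passed. PSMB9 and PSMB8, subunits of the immunoproteasome, had log2 differences of 2.43 ± 0.18 (SE) and 2.28 ± 0.13. The 1 member that fell was CD74, the invariant chain of MHC class II, with -3.34 ± 0.085. The median difference was 0.75 on the log2 scale. Without probe sets that can match several transcripts (suffix _s_at or _x_at) the adjusted p was 0.342 over 17 members. That setting also drops PSMB8, whose probe set has the suffix _s_at, so it does not isolate shared probes as the reason. Between HLA-F and TAPBP along the chromosome, 58 other genes had a value of 6 or above on at least 4 arrays. Of these, 49 were also higher in PEO4, with a median log2 difference of 0.86. A gene can pass that filter through PEO4 alone, as did SLC44A4, named after its values were seen (4.73 in PEO1 and 6.73 in PEO4). The list members were not filtered. The 16 in that neighbourhood had a median of 0.86, and the 11 elsewhere 0.10.

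**Figure D2:**
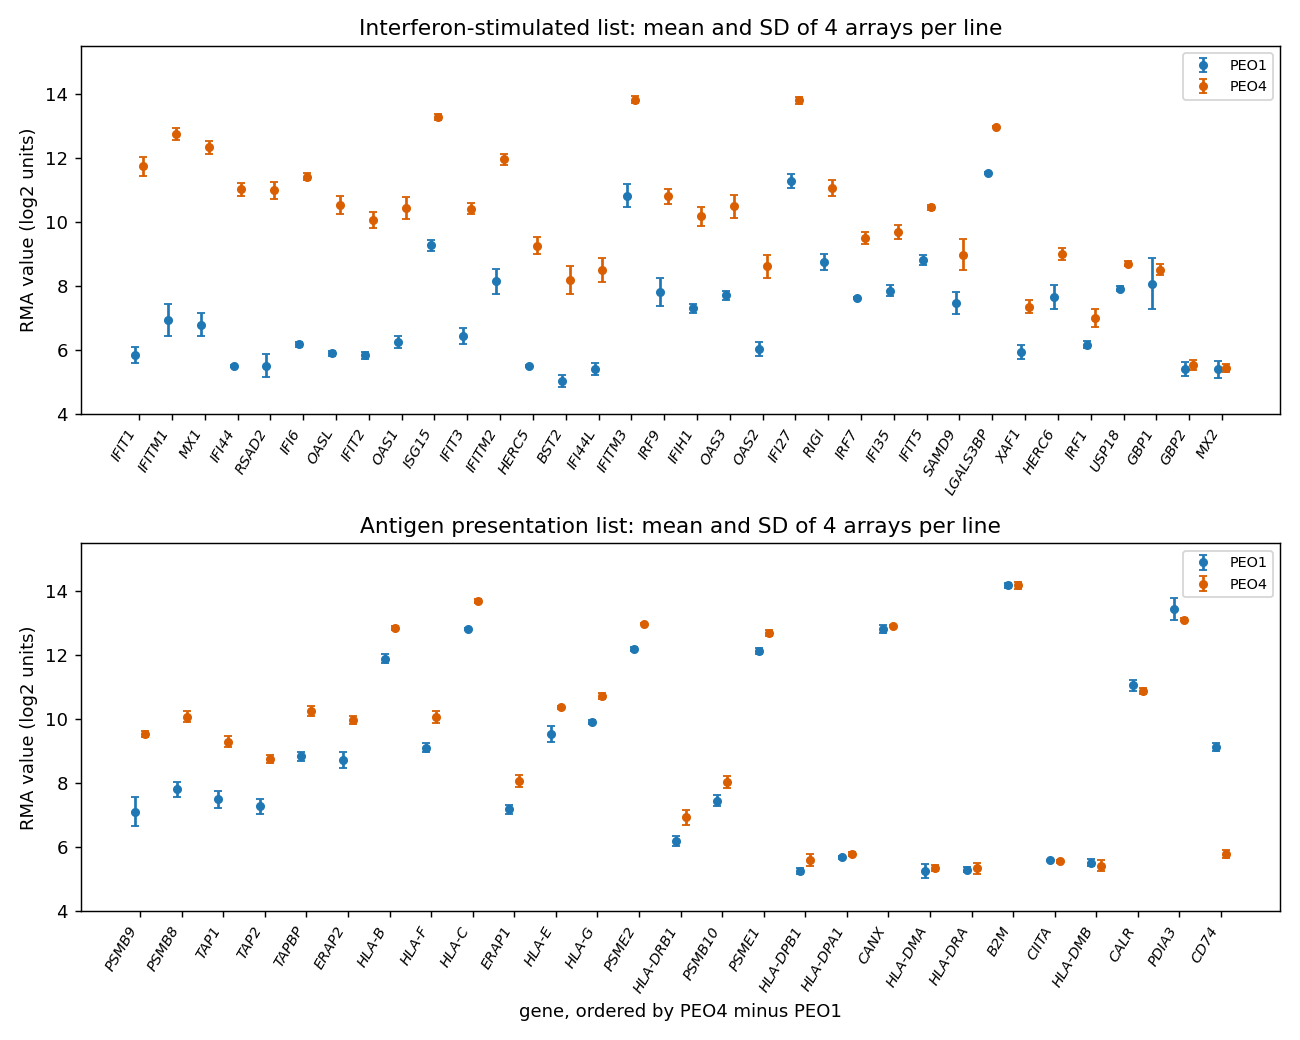
Mean RMA value (log2 units) and SD of 4 arrays per line for each measured gene of the interferon-stimulated list (top) and the antigen presentation list (bottom), ordered by the difference PEO4 minus PEO1. In the upper panel 31 of 34 genes are higher in PEO4; in the lower panel 17 of 27 are, and CD74, the rightmost, is lower.

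Genes of inflammatory signalling and of sterol synthesis differed in both directions. In the list of NF-kB cytokines and targets, 4 of the 31 measured members were higher in PEO4, 11 were lower and 16 did not pass; adjusted over the list alone, 18 passed. CXCL1, a neutrophil chemokine, and IL18 had log2 differences of -3.07 ± 0.24 (SE) and -2.94 ± 0.14. CCL5, a T cell chemokine, and NFKB1 went the other way, with 2.93 ± 0.22 and 0.79 ± 0.14; CCL5 was within the control range on 1 of its 4 PEO1 arrays. The list as a whole did not pass (camera adjusted p = 0.0883, and 0.842 with an estimated correlation), but it passed without PEO1 replicate 1 (adjusted p = 0.0477) and without PEO4 replicate 3 (0.0267). In cholesterol synthesis, 3 of the 18 measured members were higher in PEO4, 11 were lower and 4 did not pass; adjusted over the list alone, 14 passed. NSDHL, a sterol dehydrogenase, had -1.93 ± 0.073, INSIG1, a sterol-sensing regulator, -1.19 ± 0.13 (-0.79 and -0.50 on its others), and TM7SF2, a sterol reductase, 1.03 ± 0.071. This list also did not pass (camera adjusted p = 0.0589, and 0.842 with an estimated correlation); it passed without PEO1 replicate 1 (0.0354), PEO4 replicate 1 (0.0433), PEO4 replicate 3 (0.0473) or PEO4 replicate 4 (0.0289).

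DNA repair genes, which act on platinum lesions, differed one by one and in both directions. In homologous recombination, 6 of the 24 measured members were higher in PEO4, 3 were lower and 15 did not pass; adjusted over the list alone, 9 passed. RAD51C and NBN, which act at double-strand breaks, had log2 differences of 1.15 ± 0.11 (SE) and 0.82 ± 0.094; the other RAD51C probe set had 0.54. EXO1, a resection nuclease, and XRCC2 had -1.37 ± 0.10 and -0.62 ± 0.16. BRCA1 did not pass, at -0.14 ± 0.068 (limma adjusted p = 0.148), though it passed with arrays centred on housekeeping genes (0.019). Its other probe set went the other way and did not pass either (0.19). In the Fanconi anaemia and crosslink repair list, 4 of the 15 measured members were higher in PEO4, 1 was lower and 10 did not pass, 5 passing over the list alone. FANCE had 0.69 ± 0.094 and the nuclease FAN1 -0.58 ± 0.11. In nucleotide excision repair, 9 of the 23 measured members were higher in PEO4, 3 were lower and 11 did not pass, 13 passing over the list alone. GTF2H4 and XPA had 1.23 ± 0.12 and 0.56 ± 0.14, CETN2 had -1.30 ± 0.083, and ERCC1 did not pass (0.13 ± 0.080). GTF2H4 is one of the genes between HLA-F and TAPBP, where most genes were higher. Other genes named in this report may also lie among neighbours that moved together, as given for TRIB3 in the closing section. In mismatch repair, 0 of the 14 measured members were higher in PEO4, 6 were lower and 8 did not pass, 7 passing over the list alone. The 6 that fell are subunits of the replication clamp, its loader and DNA polymerase delta, which also serve replication, and include PCNA (-1.15 ± 0.10) and RFC5 (-1.04 ± 0.081). None of these 4 lists passed the test against other genes: camera adjusted p was 0.532, 0.526, 0.532 and 0.259 in the order given, and 0.842 for each with an estimated correlation.

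Transport and detoxification genes also moved both ways. Among platinum and copper transporters and efflux pumps, 2 of the 20 measured members were higher in PEO4, 6 were lower and 12 did not pass, 8 passing over the list alone. ABCC4, an organic anion efflux pump, had a log2 difference of 0.82 ± 0.090 (SE) and ABCC10 0.36 ± 0.089. LRRC8D, a subunit of volume-regulated anion channels, had -0.57 ± 0.068 and ABCC5 -0.50 ± 0.086. The copper importer SLC31A1 (-0.18 ± 0.074) and the copper exporter ATP7B (-0.01 ± 0.072) did not pass, and neither did ABCB1, which was within the control range in both lines. ATP7B lay near the top of that range in both lines (5.21 ± 0.028 and 5.20 ± 0.11, SD) and within it on 1 of its 4 PEO4 arrays, so its value says little. SLC31A1 passed without PEO1 replicate 4 (limma adjusted p = 0.0345) and with arrays centred on housekeeping genes (0.0187). In the glutathione and metallothionein list, 9 of the 30 measured members were higher in PEO4, 7 were lower and 14 did not pass, 17 passing over the list alone; its metallothionein and GSTM members are near copies of one another. GCLC and GCLM, the catalytic and modifier subunits of the enzyme that limits glutathione synthesis, went apart, at 1.09 ± 0.11 and -0.51 ± 0.074. GSTZ1 had 1.12 ± 0.11 and GSTK1 -0.99 ± 0.072. Among NRF2 targets, 3 of the 20 measured members were higher in PEO4, 3 were lower and 14 did not pass, 4 passing over the list alone, with HMOX1, a heme oxygenase, at -1.05 ± 0.22 and AKR1B10, whose PEO1 mean and 3 of 4 PEO1 arrays lay within the control range, at least 1.67-fold higher. Camera adjusted p was 0.526, 0.996 and 0.920 for these 3 lists, and 0.842, 0.998 and 0.946 with an estimated correlation.

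Among the apoptosis regulators, 8 of the 27 measured members were higher in PEO4, 5 were lower and 14 did not pass, 14 passing over the list alone. BAK1 and PMAIP1, which promote apoptosis, had log2 differences of 0.98 ± 0.12 (SE) and 0.70 ± 0.082, while HRK, also a promoter of apoptosis, had -2.41 ± 0.066 on its brightest probe set and -0.46 and -0.055 on its 2 others, the latter not past the threshold. Among the p53 targets, 5 of the 22 measured members were higher in PEO4, 4 were lower and 13 did not pass, 9 passing over the list alone. CDKN1A, an inhibitor of cyclin-dependent kinases, had 0.70 ± 0.11, and PHLDA3 and TIGAR had -0.81 ± 0.089 and -0.71 ± 0.11. Among the G2/M genes, 7 of the 29 measured members were higher in PEO4, 10 were lower and 12 did not pass, 17 passing over the list alone. The phosphatase CDC25B and the transcription factor FOXM1 had -2.19 ± 0.096 and -1.08 ± 0.080, and the mitotic genes KIF20A and TTK 1.38 ± 0.12 and 1.03 ± 0.095. MKI67 was lower on its brightest probe set (-0.61 ± 0.089), but another of its probe sets was higher (0.50, adjusted p = 0.0055 in limma) and the mean of its probe sets did not pass (-0.11, adjusted p = 0.387). Among the DNA replication genes, 5 of the 33 measured members were higher in PEO4, 8 were lower and 20 did not pass, 13 passing over the list alone. PRIM2 had 1.37 ± 0.084 (of its 2 other probe sets 1 was also higher and 1 did not pass) and MCM3 0.83 ± 0.085. PCNA and RFC4 had -1.15 ± 0.10 and -0.67 ± 0.082. Camera adjusted p was 0.893, 0.788, 0.559 and 0.615 for these 4 lists, and 0.927, 0.925, 0.925 and 0.927 with an estimated correlation.

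Among the epithelial genes, 3 of the 27 measured members were higher in PEO4, 11 were lower and 13 did not pass, 15 passing over the list alone. CDH3, P-cadherin, and KRT7, a keratin of simple epithelia, had log2 differences of -2.76 ± 0.11 (SE) and -2.66 ± 0.097 (KRT7 had -0.59 on its other probe set), and the desmosomal gene DSP 0.34 ± 0.081. Among the mesenchymal and matrix genes, 9 of the 29 measured members were higher in PEO4, 8 were lower and 12 did not pass, 17 passing over the list alone. TGFBI, a matrix protein, and the receptor tyrosine kinase AXL had -3.25 ± 0.19 and -2.27 ± 0.18 (AXL had -1.25 on its other probe set), and S100A4 had 1.34 ± 0.13. COL3A1 had 2.06 ± 0.17 on its brightest probe set, 1.63 and 0.28 on 2 others that also passed, and 0.094 (adjusted p = 0.403) on its only probe set without an _s_ or _x_ suffix. Among the Müllerian and ovarian carcinoma markers, 8 of the 22 measured members were higher in PEO4, 7 were lower and 7 did not pass, 16 passing over the list alone. EMX2, a Müllerian homeobox gene, had 4.32 ± 0.14, the kallikrein KLK5 had -2.84 ± 0.11 and MECOM was at least 3.90-fold lower, though its other probe set did not pass (-0.0038). PAX8 did not pass (0.26 ± 0.12), though 1 of its 7 other probe sets was higher (0.80). MUC16, which encodes CA-125, was lower by a margin close to the threshold (-0.54 ± 0.18, limma adjusted p = 0.0317), and did not pass without PEO1 replicate 1 (0.0891), PEO1 replicate 3 (0.0872), PEO4 replicate 1 (0.0824) or PEO4 replicate 3 (0.0567), nor with the replicate number as a block (0.0608). Camera adjusted p was 0.258, 0.826 and 0.526 for these 3 lists, and 0.842, 0.925 and 0.842 with an estimated correlation.

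Among the oestrogen response genes, 12 of the 28 measured members were higher in PEO4, 7 were lower and 9 did not pass, 19 passing over the list alone. GREB1 and PDZK1 had log2 differences of 1.97 ± 0.24 (SE) and 1.70 ± 0.15, and ADCY9 and ABCA3 -1.56 ± 0.14 and -1.37 ± 0.17. The 2 other probe sets of GREB1 (0.097 and 0.046) and the 2 of ADCY9 (-0.38 and -0.058) did not pass. The oestrogen receptor gene ESR1 did not pass (0.24 ± 0.10). Among the ErbB receptors, ligands and feedback genes, 7 of the 22 measured members were higher in PEO4, 6 were lower and 9 did not pass, 14 passing over the list alone. The ligand EREG was at least 2.03-fold higher and the MAP kinase phosphatase DUSP4 had -2.96 ± 0.15. EGFR had -2.34 ± 0.095 on its brightest probe set, and 3 of its 5 others were also lower (-2.04, -1.89 and -1.71), while the 2 without an _s_ or _x_ suffix did not pass (-0.12 and -0.072). Among the stem-like cell markers, 2 of the 22 measured members were higher in PEO4, 9 were lower and 11 did not pass, 11 passing over the list alone. Beside PROM1, the hyaluronan receptor CD44 had -2.41 ± 0.13, 5 of its 7 other probe sets being also lower and 2 not past the threshold, while NES had 1.17 ± 0.14. In the hypoxia list, 10 of the 29 measured members were higher in PEO4, 7 were lower and 12 did not pass, 17 passing over the list alone, with the angiogenic factor VEGFA at 1.96 ± 0.23, P4HA1 at 1.22 ± 0.13 and ENO2 at -1.35 ± 0.13. In the unfolded protein response, 2 of the 22 measured members were higher in PEO4, 7 were lower and 13 did not pass, 9 passing over the list alone, with TRIB3 at -2.03 ± 0.17 and XBP1 at 0.58 ± 0.13. Among the cancer-testis antigens, 3 of the 23 measured members were higher in PEO4, 1 was lower and 19 did not pass, 4 passing over the list alone. PRAME had -1.54 ± 0.12. The near-identical SSX1 and SSX2 had 1.67 ± 0.15 and 1.33 ± 0.12, and their signals cannot be assigned to one copy; the other SSX1 probe set did not pass (0.11). Camera adjusted p was 0.504, 0.996, 0.210, 0.526, 0.398 and 0.826 for these 6 lists, and 0.842, 0.998, 0.842, 0.842, 0.842 and 0.925 with an estimated correlation.

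Markers of cell types other than ovarian cancer cells were mostly low in both lines. Among the leukocyte markers, 2 of the 16 measured members were higher in PEO4, 1 was lower and 13 did not pass, with ITGB2 at 1.90 ± 0.12 (SE), CORO1A at 1.63 ± 0.077 and CD14 at -1.11 ± 0.12. Among the fibroblast markers, 3 of the 15 measured members were higher in PEO4, 3 were lower and 9 did not pass, with MFAP5 at -1.13 ± 0.25 on its brightest probe set and -0.26 and -0.42 on its others; the 3 that rose include COL3A1, on its brightest probe set. Among the endothelial markers, 3 of the 12 measured members were higher in PEO4, 0 were lower and 9 did not pass, with ENG at 0.72 ± 0.074, though its other probe set did not pass (0.47). Among the mesothelial markers, 2 of the 9 measured members were higher in PEO4, 2 were lower and 5 did not pass, with BNC1 at 0.66 ± 0.10 and KRT5, also a basal keratin, as above. Adjusted over each list alone, 3, 6, 3 and 4 members passed. The median level of a member was 5.31, 5.91, 5.15 and 5.49 for the 4 lists. Among the housekeeping genes, 3 of the 17 measured members were higher in PEO4, 4 were lower and 10 did not pass, 7 passing over the list alone. TFRC and HPRT1 had -1.08 ± 0.083 and -0.85 ± 0.073, and CYC1 and GUSB 0.95 ± 0.063 and 0.59 ± 0.087. Camera adjusted p was 0.532, 0.920, 0.504, 0.874 and 0.826 for these 5 lists, and 0.842, 0.946, 0.842, 0.925 and 0.925 with an estimated correlation. In 7 of the 29 lists the median, the mean and the camera direction did not share a sign: glutathione and metallothionein, apoptosis regulators, mesenchymal, ErbB, fibroblast, mesothelial and housekeeping.

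**Figure D3:**
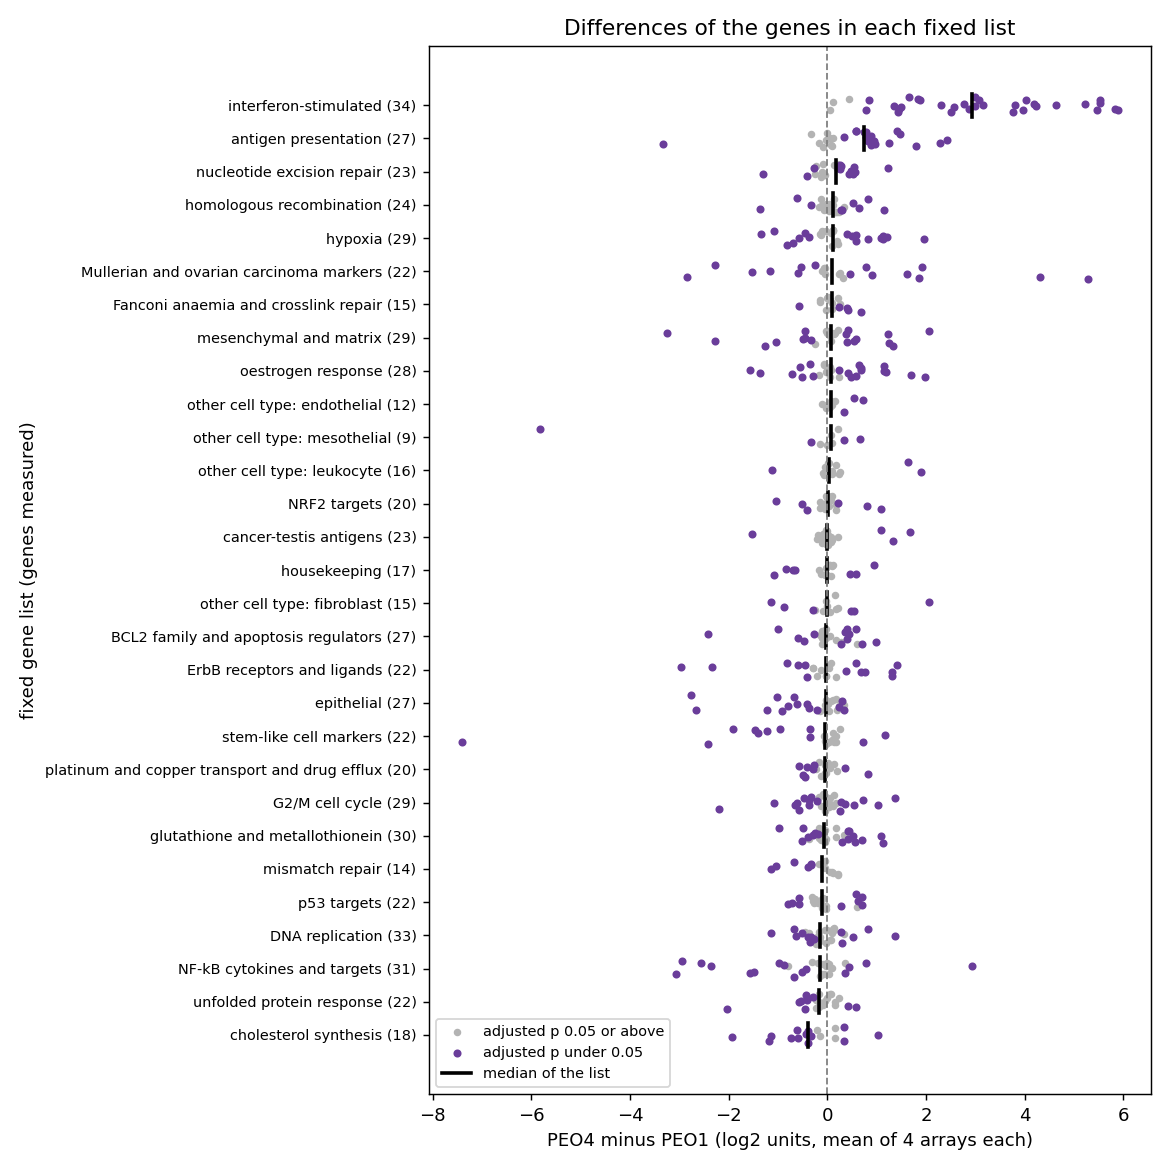
Log2 difference PEO4 minus PEO1 of each measured gene (points) in the 29 fixed lists, with the list median as a black bar and the number of genes measured in brackets; purple points passed an adjusted p under 0.05 in limma. The interferon-stimulated list has its median at 2.93 and the antigen presentation list at 0.75, and the other medians lie between -0.39 and 0.18.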

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

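Within the 4 arrays of a line, a single array lay far from the other 3 for 16 of the 306 combinations of a named gene or list and a line; chance alone gives about 15.3. Each is given with the value on that array and the mean of the other 3, in log2 units. One array was higher for ABCC10 in PEO1 replicate 1 (6.79 against 6.51), ABCC5 in PEO1 replicate 4 (8.53 against 8.33), ATP7B in PEO1 replicate 2 (5.26 against 5.20), BRCA1 in PEO4 replicate 4 (8.84 against 8.73) and CDKN1A in PEO4 replicate 2 (7.71 against 7.25). It was also higher for CRABP2 in PEO4 replicate 2 (13.46 against 13.23), DSP in PEO1 replicate 2 (10.65 against 10.51), IFI44 in PEO4 replicate 4 (11.33 against 10.92), KRT5 in PEO4 replicate 2 (6.36 against 6.25) and SDF2L1 in PEO1 replicate 1 (9.91 against 9.64). One array was lower for COL1A2 in PEO1 replicate 4 (5.44 against 5.71), EHF in PEO1 replicate 1 (9.15 against 9.96) and PMAIP1 in PEO4 replicate 1 (11.59 against 11.83). Among list means, one array was higher for the mean of the mismatch repair list in PEO4 replicate 1 (9.89 against 9.81) and lower for the mean of the nucleotide excision repair list in PEO4 replicate 4 (8.83 against 8.84) and the mean of the ErbB receptors and ligands list in PEO1 replicate 4 (7.83 against 7.88). Leaving out the array in question ended none of the calls of these genes.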

How the results depend on the processing

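The number of genes that differed (4605), the numbers higher and lower, and the number at least 2-fold kept within 1.5 times of their values under all alternatives but 2. Testing all 22215 probe sets separately gave 7405 calls, 3688 higher and 3717 lower, with 1443 at least 2-fold. Without _s_at and _x_at probe sets, 8507 genes were tested and 2794 differed, 1411 higher and 1383 lower, with 581 at least 2-fold. Of the 2700 genes called both there and in the main test, 10 had the opposite direction. These settings test more and fewer features, and the cause of the changed counts was not tested. Leaving out 1 array gave 4159 to 4406 genes, 2103 to 2255 higher, 2037 to 2151 lower and 926 to 951 at least 2-fold. Centring on housekeeping genes gave 4881, with 1777 higher and 3104 lower, and a test against 1.5-fold gave 1076 genes in place of the 937 at least 2-fold. The replicate block gave 4246 genes, 2168 higher and 2078 lower. The deviations of same-numbered arrays correlated at 0.012, 0.037, -0.191 and -0.149 and 0 of 8 arrays correlated best with their own number, so the numbers were not taken as pairs. The block ended the calls of MUC16 (adjusted p = 0.0608) and UPK3B (0.0643) among the named genes and changed no list's call. The interferon-stimulated and antigen presentation lists both lost their call with an estimated correlation (adjusted p = 0.264 and 0.264). The antigen presentation list also lost it without _s_at and _x_at probe sets (0.342). The cholesterol synthesis list passed with the mean of a gene's probe sets (0.0476), and ranged from 0.0289 to 0.11 over arrays left out; the NF-kB list ranged from 0.0267 to 0.223. The cause of these changes of lists was not tested. For single named genes, 20 of 992 values with an array left out lost their call and 1 gained one; under the other settings 10 of 949 lost it and 2 gained one, and none reversed. The array has no detection calls here, so low values are limited by background near 4.34 to 5.18.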

Other observations

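For the interferon list, the tests of shared probes and leukocytes were chosen after the differences were known. So were the 3 tests of the antigen presentation list and all tests of the squamous list, both its median and its share of lower members. The test of the interferon genes themselves and the scan of windows of neighbouring genes should be read in the same way.

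The differences between the lines ran in blocks of neighbouring genes. Along the chromosomes, the order of 7520 genes with a value of 6 or above on at least 4 arrays was used. Among windows of 41 consecutive genes, the window from PTK2 to C8orf33 had 41 of 41 genes higher in PEO4, with a median log2 difference of 1.09. The window from PRRC2A to TAPBP had 40 of 41 higher (median 1.06), that from CDC5L to TENT5A 38 of 41 (0.98) and that from ACVR2A to PDK1 40 of 41 (0.93). The most negative windows ran from MAP7D3 to SLC10A3 (37 of 41 lower, median -1.05), from TRIB3 to BTBD3 (40 of 41 lower, -0.98), from CSDC2 to MAPK12 (37 lower, -0.95) and from H2AC25 to ZNF692 (38 lower, -0.90). The largest window median in 1000 shuffled orders was 0.57 in size, and 606 of the 6600 overlapping windows lay beyond it, 450 higher and 156 lower. TRIB3, named above in the unfolded protein response list, is the first gene of a window with 40 of 41 genes lower. Other named genes may lie in such windows too, and their differences were not separated from those of their neighbours.

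Log2 differences of genes 10 places apart had a Spearman correlation across genes of 0.223, above the highest of 1000 shuffled orders (0.044; p = 0.001, the smallest they can give; genes are not independent replicates). With both genes measured by a probe set without an _s_ or _x_ suffix, the correlation was 0.210 against a highest shuffled value of 0.061, which argues against probes shared within gene families as the source. A candidate explanation is a set of regional differences such as DNA copy number between the lines; copy number was not measured here, so regional regulation stays open.

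Part of the rise of the antigen presentation genes may belong to such a block. Between HLA-F and TAPBP, 58 genes of neither this list nor the interferon list had a value of 6 or above on at least 4 arrays. They had a median log2 difference of 0.86 (95% bootstrap interval 0.71 to 1.03), and 49 of them rose. The bootstrap intervals in this section resample genes, which are not independent replicates, so they do not measure the spread between arrays. MDC1, a mediator of the DNA damage response, SLC39A7, a zinc transporter, and PBX2, a homeobox gene, named after their values were seen, had 1.53 ± 0.086, 1.52 ± 0.19 and 1.30 ± 0.12 (SE); other probe sets of MDC1 and PBX2 had smaller differences, 0.68 for MDC1 and 0.028 to 0.64 for PBX2. The median of list members outside that neighbourhood was 0.10 (-0.17 to 0.78), with 5 of 11 higher, which leaves open a rise of the list wherever its genes lie. The 17 members that have a probe set without an _s_ or _x_ suffix had a median of 0.12 (-0.12 to 0.59) on it. Of these, 7 rose, among them PSMB9 and, named after their values were seen, TAP2, TAPBP and ERAP2. For these genes probes shared between HLA transcripts are no explanation. PSMB9, TAP2 and TAPBP lie in that neighbourhood, so their rise was not separated from that of the other genes there. Other probe sets had smaller differences, 0.98 and -0.072 (not past the threshold) for TAP2 and 0.41 for TAPBP. Of the 6 HLA genes among the 17, 1 rose, so shared probes stay open for the HLA members measured through suffixed probe sets.

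For the interferon-stimulated genes, shared probes are argued against by the 26 members with a probe set that has no _s_ or _x_ suffix, whose median log2 difference was 2.83 (95% bootstrap interval 1.47 to 3.87), 23 of them higher. Leukocytes among the PEO4 cells are argued against by a median of 0.036 (-0.054 to 0.18) over 16 leukocyte markers; the brightest of them, CORO1A, reached 10.47 in PEO4 and rose, as did ITGB2, while 13 did not pass and 1 fell. Of 15 interferon genes on the array, 0 passed the threshold in limma and 0 had an unadjusted p under 0.05; the largest positive difference was 0.084 (IFNG), and the largest in size was -0.13 (IFNW1, which also had the highest PEO4 mean, 5.58). Since a ligand can act at a level the array does not measure, interferon made by PEO4 cells stays open, as does any difference in culture that the labels do not record. A standing interferon response in PEO4 is a hypothesis that these tests leave in place.

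The other ways of splitting the 8 arrays into 4 and 4 were tried for the counts. Only 1 of 35 splits, the real one, gave as many as 4605 genes, 2336 higher, 2269 lower or 937 at least 2-fold, and the highest count in any other split was 0. A share of 1 in 35 is the smallest this design can give, and each other split mixes the lines, which widens the spread within its groups. For the number of gene lists past the threshold (2), 23 of 35 splits gave as many, up to 5, but 16 of them put 3 arrays of a line against 1 and keep part of the real difference, so that count is not one of chance alone. Of the 18 splits that put 2 arrays of each line on each side, 6 gave as many, up to 3, so chance is not excluded for that number at the preset correlation. For the interferon-stimulated list itself 1 of 35 splits gave a camera p as small as 3.88e-28, the lowest other being 7.27e-12; for antigen presentation 1 of 35 gave 1.82e-06, the lowest other being 3.4e-05. Both of these others put 3 arrays of a line against 1; with 2 against 2 the lowest were 0.077 and 0.10.

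Some of the large decreases are genes of stratified squamous epithelium, such as KRT5 and CALML3 at log2 differences of -5.84 and -4.46 and FLG, at least 11.2-fold lower; the other CALML3 probe set did not pass (0.21). A lower squamous-like program in PEO4 was tested as a hypothesis on a list of 30 measured genes written after those values were seen, and it stays open. The list holds KRT5, CALML3 and FLG themselves. Its counts and medians therefore partly repeat the values that prompted it and are no independent support. Of the 30, 12 fell, 6 rose and 12 did not pass. The list median of -0.022 lay at percentile 31.5 of 10000 random lists matched on mean value. The prediction written for this test asked for a median below 95% of the random lists, so it was not met. That rule was not used alone to reject the hypothesis, because members near background in both lines cannot fall. The 17 members at 6 or above on at least 4 arrays had a median of -0.68 (95% bootstrap interval -2.04 to 0.14). Among the 14 of them past the threshold, 71.4% were lower. That filter keeps FLG (8.67 in PEO1 and 5.02 in PEO4) and CALML3 (10.08 in PEO1 and 5.62 in PEO4) through their PEO1 arrays. The share therefore does not settle whether the floor of the array shaped the count. TGM1, S100A2 and DSC3 were higher in PEO4, at 2.21, 1.92 and 1.60. Of the 2491 probe sets without a single gene symbol, 624 also passed the threshold, 281 higher and 343 lower.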
